A study of Mus musculus with 6 samples.

How the data were processed

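RNA from 6 samples of sorted day 4 cells was hybridised to 1 array each, 3 controls and 3 with HOXB4. Per the labels' protocols, RNA was extracted with Trizol and a column, and 100 ng was labelled with the Affymetrix WT PLUS kit. The deposited values are log2 expression summaries made by the authors, and per the submitters' processing notes the tools were Affymetrix Expression Console and RMA, a method that by design corrects background, normalises quantiles between arrays and summarises probes. Their versions, settings and annotation are not given in the sources used here. The highest deposited values, up to 19.9 on the log2 scale, exceed what a 16 bit scanner can give, so the intensities may have been rescaled and a value is comparable between arrays but has no absolute meaning. RMA equalises the arrays, so a shift of most genes in one direction would be partly removed before these values.

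The table held 65956 features that were not control features. After symbols of the platform annotation were brought up to date through a RefSeq gene table of assembly GRCm38.p6, 31258 features named 1 gene, 1492 named several and 33206 had no listed gene, which here means unnamed. The brightest single-gene feature stood for each of the 30702 genes, of which 441 had several. Features that name several genes were not used for genes, apart from those listed for Hoxb4 and Pdgfra. The depth of an array was judged by signal over background: 23 antigenomic background features had medians of 3.06 to 3.15, against 5.10 to 5.22 for the median gene.

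Groups came from the sample titles, and the series text states that the 3 replicates are independent experiments. HOXB4 minus control was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes; two-sided, Benjamini-Hochberg adjusted p below 0.05), with no replicate block. SE is the moderated standard error. Gene lists were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over 29 lists, beside camera with an estimated correlation and fry. Of 679 list entries, 615 were measured, and 31 genes stood in more than 1 list. The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule named Hoxb4, Runx1, the 12 genes per direction with the largest change among those that passed without overlap or, with fewer than 5, the 8 per direction with the smallest unadjusted p, and up to 4 genes per list with the smallest p. Predicted, clone, microRNA and receptor-cluster genes were left out of the second part. Plots and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

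The steps were tested on simulated data with the real means and moderated SDs of the 30702 genes for HOXB4 against control. Of 100 genes changed 2-fold, 77% were recovered, and of 100 changed 4-fold, 96%; 12 of the unchanged genes were called. A list shifted by 0.5 on the log2 scale was found, with 1 unshifted list also called. For these genes and lists the noise was independent between genes, without the axis shared by many genes in the real arrays. The shares recovered are therefore not the power of the real comparison. In 100 draws without a group effect, in which the scores of the first principal component were dealt to the arrays at random, camera with the preset correlation called 2.36 lists on average, and 10 or more in 10 draws. With an estimated correlation it called 0. Apart from that component, the noise in these draws was independent between genes as well. Splits of the 6 real arrays other than the labelled one called 0 to 12 lists at the preset correlation. The counts in the draws are therefore not the number to be had without an effect in these arrays. Alternatives were the replicate number as a block, other priors, array weights, a filter on dim features, 2 other scalings, other rules for features, other tests, each array left out in turn, and 2 fits chosen after the data were seen. No sample was left out of the main comparison.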

Results

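Gene expression was measured in mouse embryonic stem cells of a line the labels call iRunx, differentiated as embryoid bodies, aggregates in which the germ layers form. At day 4 the bodies were dissociated, and cells positive for Flk1 and negative for PDGFRα, a fraction that holds precursors of endothelium and blood, were sorted by flow cytometry. One group of cells expressed HOXB4, a homeodomain protein used to expand blood progenitors, from a retrovirus marked with tdTomato, and the other did not; whether the latter carried an empty vector is not given in the sources used here. Each group had 3 arrays, which the labels describe as independent experiments, and the comparison asks what HOXB4 changes in these cells. Values were log2 RMA summaries for 30702 genes. The median gene lay between 5.10 and 5.22 in the 6 arrays, and the background features of the array had medians between 3.06 and 3.15. The number of arrays limits the precision of every value given here.

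The transgene itself could not be read from the array. The 1 feature listed for Hoxb4 is also listed for the microRNA gene Mir10a, so it does not measure Hoxb4 alone. It averaged 4.66 ± 0.28 (SD, n = 3) in controls and 4.64 ± 0.36 (SD, n = 3) in HOXB4 cells, a log2 difference of -0.03 (SE 0.21). Its values were 4.63, 4.96 and 4.40 in controls 1 to 3 and 4.93, 4.24 and 4.74 in HOXB4 1 to 3. The labels do not name the species of the introduced HOXB4, so this feature does not check the labels. Runx1 was at 5.85 ± 0.37 in controls and 5.85 ± 0.14 in HOXB4 cells (SD, n = 3 each), and the sign of its difference of 0.004 (SE 0.19) turned between settings. The name of the line points to an inducible Runx gene, and whether one was induced is not given in the sources used here, so the Runx1 value is not read as that of the endogenous gene alone. Kdr, which encodes the sorting marker Flk1 and was looked up after the values were seen, differed by 0.06 (SE 0.19), by -0.14 without HOXB4 1 and by 0.19 without HOXB4 2. The feature listed for Pdgfra, the marker sorted against, is also listed for Mir7025, and it stood at 6.67, 6.47 and 6.89 in controls 1 to 3 and at 5.95, 7.15 and 6.04 in HOXB4 1 to 3, highest in HOXB4 2.

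In HOXB4 cells the cardiac and Hox cluster genes lay lower, while endothelial genes and blood transcription factors lay higher on average. With an estimated correlation none of these 4 shifts was called (adjusted p = 0.93 for the endothelial list and 0.55 for each of the other 3), and without HOXB4 1 the endothelial mean turned to -0.07. HOXB4 2 shared the lower Hox cluster values and, less far, the lower cardiac ones, but its means of the endothelial genes and blood transcription factors lay below those of every control. Hand1, a transcription factor of heart and extra-embryonic mesoderm, averaged 13.4 ± 0.49 in controls and 10.1 ± 2.34 in HOXB4 cells (SD, n = 3 each), because HOXB4 2 stood at 12.8 and HOXB4 1 and 3 at 8.98 and 8.61. No gene passed limma's moderated test at a Benjamini-Hochberg adjusted p of 0.05; the smallest adjusted p was 0.605. At an unadjusted p of 0.05, 2513 genes were counted, 685 higher and 1828 lower, where the other 9 splits of the 6 arrays gave 439 to 4338. The linear model without moderation also called 0 genes, with 1974 at that unadjusted level. The lean to lower values was less with cyclic loess (866 higher and 1598 lower) and absent over all features (3061 higher and 2917 lower). All 3 HOXB4 values lay above all 3 control values for 995 genes (3.24%) and below them for 3145 genes (10.2%), together 13.5% of the genes, where the other 9 splits of the 6 arrays gave 4.83 to 19.1%. Without HOXB4 replicate 2, limma called 46 genes, 43 of them lower. They included Hand1 (log2 difference -4.56), Foxf1 (-3.04), Bmp7 (-3.48) and Cdh11 (-2.88), of which Cdh11 was chosen for mention after its values were seen.

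The genes with the smallest unadjusted p were named although none passed. Among those lower in HOXB4 cells, Capn6, a calpain family member, differed by -1.36 (SE 0.16), which is 2.56-fold. Tbx4, a T-box factor of the hindlimb and allantois, differed by -1.52 (SE 0.25), and Mmp2, a secreted gelatinase, by -1.01 (SE 0.18). The histone variant genes Macroh2a2 and Macroh2a3 differed by -0.73 (SE 0.13) and -0.46 (SE 0.08). The cilium genes Cfap300 and Ift22 differed by -0.80 (SE 0.14) and -0.49 (SE 0.08), and Siva1, a pro-apoptotic factor, by -0.51 (SE 0.09). Among those higher, Eid3 differed by 1.47 (SE 0.30), and Tmem63a, Ttc39b and Acr by 0.64, 0.61 and 0.55 (SE 0.14, 0.11 and 0.10). Omd, Anxa1, an immunoglobulin heavy chain variable segment and Syngr1 differed by 0.49, 0.45, 0.43 and 0.41 (SE 0.09, 0.09, 0.09 and 0.08). The values of the immunoglobulin segment, 2.35 to 2.93, all lay below the background medians of 3.06 to 3.15, so its difference is not read as expression. The 3 HOXB4 values did not overlap the 3 control values for any of these 16 genes, which their choice by smallest p favours. Each had an adjusted p of 0.605.

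**Figure D1:**
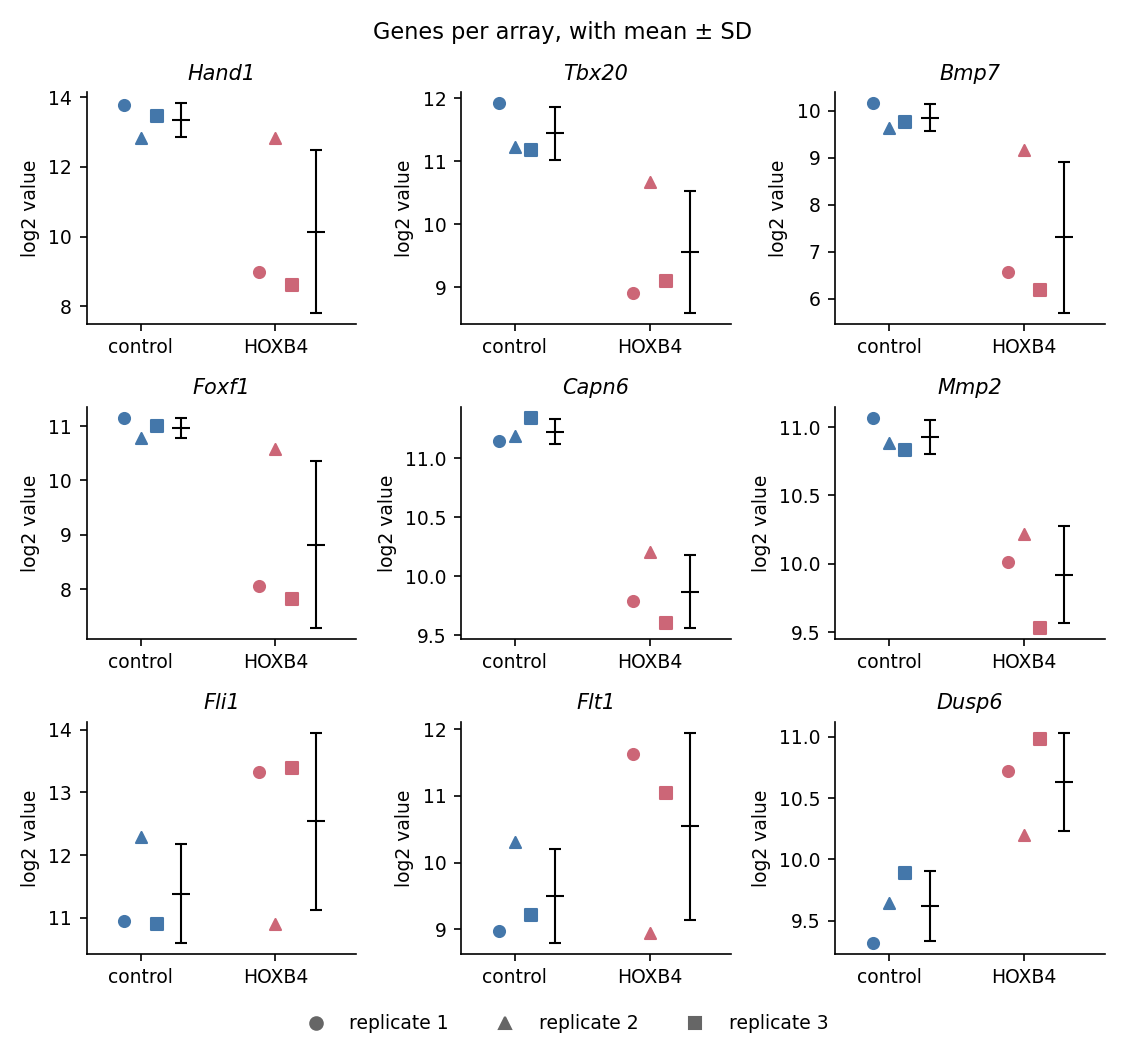
Log2 values of 9 genes in each array, controls on the left and HOXB4 cells on the right of each panel, with the mean and SD beside them (n = 3 each). HOXB4 2 lies among the controls for Hand1 (12.8). It lies near but below the lowest control for Bmp7 (9.16 against 9.63) and Foxf1 (10.58 against 10.78). The groups do not overlap for Tbx20, Bmp7, Foxf1, Capn6, Mmp2 and Dusp6, and they overlap for Hand1, Fli1 and Flt1.

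Of the 29 gene lists fixed beforehand, 10 were called by camera with its preset correlation, 4 lower and 6 higher in HOXB4 cells. None of the 10 was called with an estimated correlation (smallest adjusted p = 0.55) or by fry (smallest adjusted p = 0.20). With an estimated correlation, camera called 0 lists in every split of the 6 arrays. That held also for the split with 628 genes and 12 lists at the preset correlation. Whether it can find a shift with so few arrays was not tested, so a missing call does not decide for or against a shift. No member of any list passed over all genes. Adjusted over the list alone, 0 members of the 10 lists passed. Control 2 and HOXB4 2 stood apart from the rest of their groups in several lists. None of the 6 lists shifted up was called with cyclic loess, and of these 6 the immediate-early list alone was called with all features tested.

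The 33 measured Hox cluster genes all had differences below 0, with a mean of -0.27, and the list was shifted down (adjusted p = 3.1e-06; adjusted p = 0.55 with an estimated correlation). Of these genes, 12 had no overlap between groups, and Hoxb2 differed by -0.70 (SE 0.15), Hoxb6 by -0.88 (SE 0.23) and Hoxd13 by -0.58 (SE 0.17). The list mean was 4.54, 4.59 and 4.32 in the controls and 4.16, 4.29 and 4.17 in HOXB4 cells. Of the 33 members, 30 lay below the median gene in mean level, and with the filter on dim features the mean difference was -0.44. That filter kept genes at or above the array median of all features in at least 3 arrays. The 3 controls alone can meet it, as for Hoxb6 (5.64, 5.71 and 4.84 in controls, 4.50, 4.63 and 4.42 in HOXB4 cells). The larger difference is therefore partly selected and is no separate support. A shared sign is not particular to the labelled groups. With controls 1 and 2 and HOXB4 2 set against the rest, 32 of the 33 members lay on one side. The 21 measured cardiac genes were shifted down (adjusted p = 0.0050; adjusted p = 0.55 with an estimated correlation), with 18 below 0 and a mean of -0.50. Hand1 differed by -3.22 (SE 1.06), and Tbx20 and Hand2, further cardiac transcription factors, by -1.89 (SE 0.48) and -1.21 (SE 0.31). Smarcd3, a subunit of cardiac chromatin remodelling complexes, differed by -0.54 (SE 0.17). The cardiac list mean of HOXB4 2, 6.09, lay closer to the controls (6.15 to 6.46) than to HOXB4 1 and 3 (5.62 and 5.64). All 18 measured cytosolic ribosomal protein genes lay below 0, with a mean of -0.15 (adjusted p = 0.0025; adjusted p = 0.55 with an estimated correlation), among them Rps20 at -0.34 (SE 0.09) and Rps7 at -0.22 (SE 0.09). These 3 lists were called whichever array was left out and with arrays centred on their medians, and they were the only ones called with cyclic loess. The 33 cell cycle genes, 24 of them below 0 with a mean of -0.13, were shifted down (adjusted p = 0.029; adjusted p = 0.55 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, differed by -0.36 (SE 0.08), the replication licensing factor Cdc6 by -0.59 (SE 0.14) and cyclin gene Ccnd2 by -0.69 (SE 0.19). That call ended without control 2 (adjusted p = 0.19), control 3 (0.18) or HOXB4 3 (0.060), within a range over alternatives from 0.0042 to 0.55. Random lists matched on mean level, a test chosen after the values were seen, leaned lower too. Their medians averaged -0.059 for the ribosomal list, whose own median was -0.15 (percentile 5.1). For the cell cycle list they averaged -0.083, against -0.11 (percentile 32.2).

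The 33 endothelial genes were shifted up (adjusted p = 0.011; adjusted p = 0.93 with an estimated correlation), with 28 above 0 and a mean of 0.38. Fli1 and Flt1 differed by 1.15 (SE 0.72) and 1.04 (SE 0.70). The members with the smallest p pointed down, Arhgap29 at -0.76 (SE 0.23) and Aplnr, an apelin receptor, at -1.01 (SE 0.39). Aplnr was at -0.63 without HOXB4 3, and its value in HOXB4 2, 10.8, lay within the controls (10.7 to 11.2). HOXB4 2 lay below every control for Fli1 and Flt1, which differed by 1.97 and 1.84 without it; without HOXB4 1 they differed by 0.76 and 0.50, and Fli1 by 0.73 without HOXB4 3. The endothelial list mean was 7.38, 8.30 and 7.21 in the controls and 8.92, 7.07 and 8.06 in HOXB4 cells, so HOXB4 2 had the lowest value and control 2 the second highest. The endothelial call ended without control 1 (adjusted p = 0.23), control 3 (0.20) or HOXB4 1, where the mean turned to -0.07 (adjusted p = 0.43); the mean was 0.17 without control 3, 0.72 without control 2 and 0.85 without HOXB4 2, and over all alternatives the adjusted p ran from 5.0e-15 to 0.93. The 24 haematopoietic transcription factors, 17 above 0 with a mean of 0.24, were shifted up (adjusted p = 0.011; adjusted p = 0.55 with an estimated correlation). Etv2, which starts the blood and endothelial programme, differed by -1.53 (SE 0.60) and Mycn by 0.28 (SE 0.12), or 0.16 without control 1. Etv2 in HOXB4 2 was 12.06, within the controls (11.75 to 12.33), against 9.58 and 10.16 in HOXB4 1 and 3. The mean of these factors was 7.14, 7.47 and 7.20 in the controls and 7.77, 7.12 and 7.65 in HOXB4 cells, so HOXB4 2 had the lowest value of the 6 arrays. This call ended without control 1 (adjusted p = 0.20) or HOXB4 1 (0.27), in a range from 1.4e-06 to 0.74, and the mean difference was 0.12 without HOXB4 1 and 0.44 without HOXB4 2. The 18 pluripotency genes, 13 above 0 with a mean of 0.37, were shifted up (adjusted p = 0.011; adjusted p = 0.55 with an estimated correlation), with Zfp42 at 0.69 (SE 0.23), Utf1 at 0.73 (SE 0.29) and Tbx3 at -1.07 (SE 0.45). Without HOXB4 3 these 3 genes were at 0.43, 0.39 and -0.62, and Tbx3 was at -1.61 without HOXB4 2, which lay among the controls. The call ended without control 2 (adjusted p = 0.061) or HOXB4 2 (0.055), in a range from 9.3e-04 to 0.74.

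The 21 immediate-early and dissociation stress genes, 16 above 0 with a mean of 0.42, were shifted up (adjusted p = 0.011; adjusted p = 0.55 with an estimated correlation). Zfp36 differed by 1.67 (SE 0.65), with HOXB4 2 at 8.92, below control 3 (9.39). In contrast the heat shock gene Hsph1 was at -0.75 (SE 0.24), or -0.50 without control 1. The heat shock genes Dnajb1 and Hspa1a were also lower, at -0.28 (SE 0.10) and -0.49 (SE 0.20). Of the 21 members, 0 had every HOXB4 value above every control value, while 4 had every HOXB4 value below. The call ended without control 1 (adjusted p = 0.33), control 2 (0.083) or HOXB4 1 (0.21), in a range from 3.1e-06 to 0.74, and the mean was 0.25 without control 1, 0.68 without control 3 and 0.24 without HOXB4 1. The 22 cell cycle inhibitors and p53 targets, 16 above 0 with a mean of 0.14, were shifted up (adjusted p = 0.017; adjusted p = 0.55 with an estimated correlation), with Trp53inp1 at 0.45 (SE 0.14) and Cdkn1c at -0.96 (SE 0.32), or -0.63 without HOXB4 1. The call ended without control 1 (adjusted p = 0.20) or HOXB4 1 (0.40), in a range from 0.0016 to 0.82, and the mean was 0.07 without HOXB4 1 and 0.21 without HOXB4 2. The 35 cell adhesion and migration genes, 22 above 0 with a mean of 0.12, were shifted up (adjusted p = 0.017; adjusted p = 0.55 with an estimated correlation). Icam1 differed by 0.63 (SE 0.22) and the chemokine receptor gene Cxcr4 by -2.38 (SE 0.82). Cxcr4 in HOXB4 2 was 8.60, near control 3 (8.66), against 5.12 and 6.13 in HOXB4 1 and 3. The adhesion list mean was 8.39, 8.80 and 8.54 in the controls and 8.92, 8.52 and 8.66 in HOXB4 cells, so HOXB4 2 lay below controls 2 and 3. The call ended without control 1 (adjusted p = 0.33) or HOXB4 1 (0.31), with array weights (0.072) and with arrays centred on their medians (0.052), in a range from 0.0035 to 0.82. The mean difference fell to 0.03 without control 1 and 0.01 without HOXB4 1, and was 0.23 without control 2 and 0.21 without HOXB4 2.

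**Figure D2:**
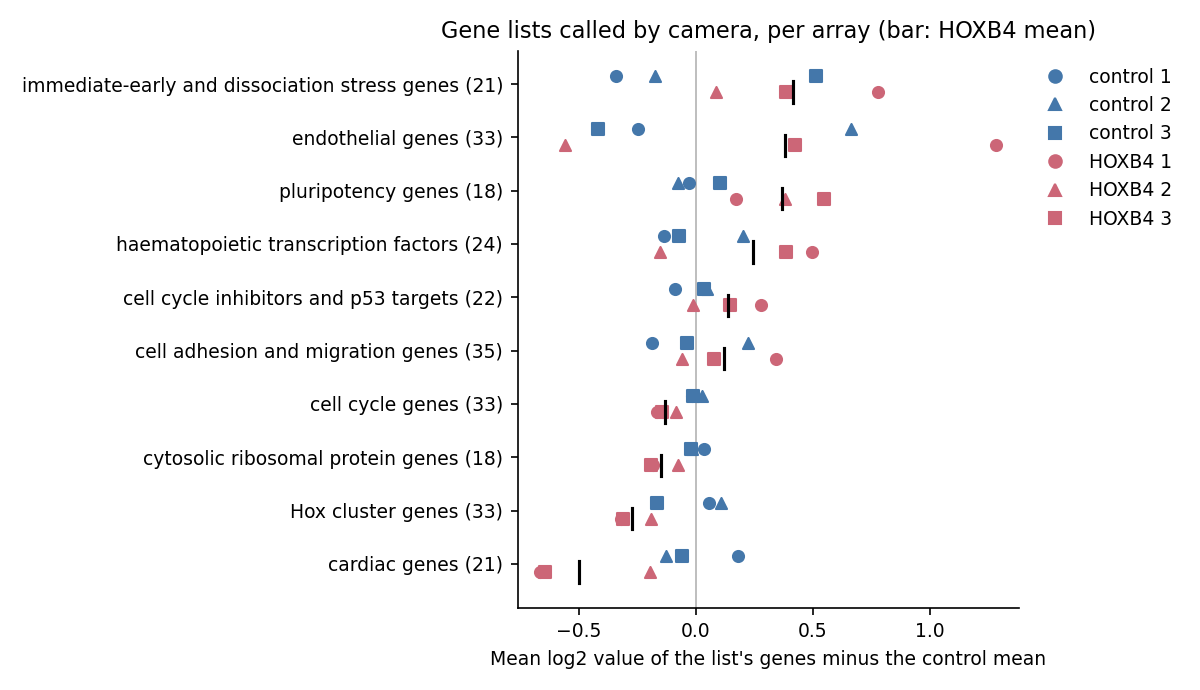
Mean log2 value of the measured genes of each of the 10 called lists in every array, minus the control mean, with the number of measured genes in brackets and a bar at the HOXB4 mean. The Hox cluster, cardiac, ribosomal and cell cycle lists lie to the left of 0 in all 3 HOXB4 arrays, and HOXB4 2 has the lowest endothelial value.

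The other 19 lists were not called. The smooth muscle and stromal list had a mean of -0.43 (adjusted p = 0.19). In it the pericyte gene Rgs5 was at -2.96 (SE 1.13) and Snai2 at -1.03 (SE 0.33), or -0.67 without control 1. Rgs5 in HOXB4 2 was 10.98, within the controls (10.26 to 11.79), against 6.99 and 6.70 in HOXB4 1 and 3. The BMP and TGF-beta list had a mean of -0.36 (adjusted p = 0.21), with Bmp7 at -2.55 (SE 0.73) and the BMP target Msx2 at -2.05 (SE 0.82), which was -3.07 without HOXB4 2 and -1.32 without HOXB4 3. The primitive streak and early mesoderm list had a mean of -0.34 (adjusted p = 0.64), with Cdx2 at -1.71 (SE 0.48) and Lhx1 at 0.92 (SE 0.33), or 0.54 without HOXB4 3. The primitive streak mean was 7.36, 7.36 and 7.62 in the controls and 6.53, 8.04 and 6.75 in HOXB4 cells, so HOXB4 2 lay above every control. Without HOXB4 2 these 3 lists were called, with means of -0.66, -0.47 and -0.81, as were the WNT (-0.29) and haemogenic surface marker (0.39) lists. Without HOXB4 1 the primitive streak, WNT and haemogenic means were -0.05, -0.03 and 0.08, and without HOXB4 3 the primitive streak, BMP and WNT means were -0.16, -0.24 and -0.09; the haemogenic mean was 0.10 without control 1 and 0.34 without control 2. The BMP and TGF-beta list was also called without HOXB4 1 (mean -0.39, adjusted p = 0.023), as was the unfolded protein list (mean -0.14, adjusted p = 0.044). Among PDGFRA-lineage and paraxial mesoderm genes (mean -0.22, adjusted p = 0.64), Foxf1 differed by -2.16 (SE 0.69) and Twist1 by -0.73 (SE 0.22), or -0.48 without control 1. With the filter on dim features, which 1 group alone can meet, this list had a mean of -0.57 (adjusted p = 0.34). The smooth muscle and haemogenic means were then -0.65 and 0.37 (adjusted p = 0.080 and 0.15). In the FGF and MAPK feedback list (mean 0.03, adjusted p = 0.27), 3 members passed when adjusted over the list alone and 0 over all genes. They were Dusp6, a phosphatase induced by ERK signalling (1.02, SE 0.23), the receptor gene Fgfr2 (-0.85, SE 0.20) and Fgf3 (-1.88, SE 0.51). The FGF list was called without control 3 (mean 0.13, adjusted p = 0.039) or HOXB4 1 (mean 0.14, adjusted p = 0.040), while its mean was -0.09 without HOXB4 2 (adjusted p = 0.66). Mean differences of the WNT, neural and ectoderm, erythroid and arterial lists were -0.14, -0.16, -0.15 and -0.16 (adjusted p = 0.86, 0.64, 0.73 and 0.79). Wnt2 differed by -0.68 (SE 0.20) and Tubb3 by 1.95 (SE 0.62). Tubb3 in HOXB4 2 was 8.25, below control 3 (8.33), against 10.20 and 10.38 in HOXB4 1 and 3. When 1 array was left out, the neural mean ran from -0.30 (without HOXB4 2) to -0.02 (without HOXB4 1), the erythroid from -0.34 (without HOXB4 2) to -0.06 (without HOXB4 3) and the arterial from -0.26 (without HOXB4 1) to -0.09 (without control 2). The haemogenic and progenitor surface markers had a mean of 0.22 (adjusted p = 0.18), the megakaryocyte list 0.08 (adjusted p = 0.74) and the endoderm list 0.07 (adjusted p = 0.64). The megakaryocyte mean turned to -0.06 without control 1 and was 0.22 without control 3, and the endoderm mean was 0.04 without control 2. Venous and lymphatic genes, glycolysis and hypoxia genes and Hox cofactors had means of -0.09, -0.06 and -0.05 (adjusted p = 0.93, 0.64 and 0.74). The venous mean ran from -0.16 (without HOXB4 1) to -0.0008 (without HOXB4 3), and without control 2 the glycolysis and cofactor means were -0.11 and -0.12, while both turned to 0.01 without control 3. Interferon-stimulated, unfolded protein, myeloid and Notch lists had means of -0.02 each (adjusted p = 0.42, 0.64, 0.86 and 0.64), and each moved when 1 array was left out. The interferon mean was -0.16 without HOXB4 2, -0.12 without control 2 and 0.07 without control 3, where the list was called (adjusted p = 0.041), and the unfolded protein mean turned to 0.07 without HOXB4 2. The Notch mean was -0.08 without HOXB4 1 and 0.01 without HOXB4 3, and the myeloid mean ran from -0.04 (without control 3) to 0.003 (without control 1). Camera's direction was up although the mean was below 0 for the arterial, Hox cofactor, interferon, myeloid, Notch and WNT lists, and median and mean differed in sign for the arterial, endoderm, FGF, megakaryocyte and Notch lists.

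The leading axis of the 6 arrays did not follow the groups. The first principal component held 53.2% of the variance between arrays, with scores of -37.1, 7.46 and -25.0 for controls 1 to 3 and 43.8, -23.8 and 34.7 for HOXB4 1 to 3. HOXB4 2 thus lay with controls 1 and 3. The second component held 18.2% and did not part the groups either, with controls at 22.0, 24.5 and -21.3 and HOXB4 cells at -9.49, -18.2 and 2.46.

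**Figure D3:**
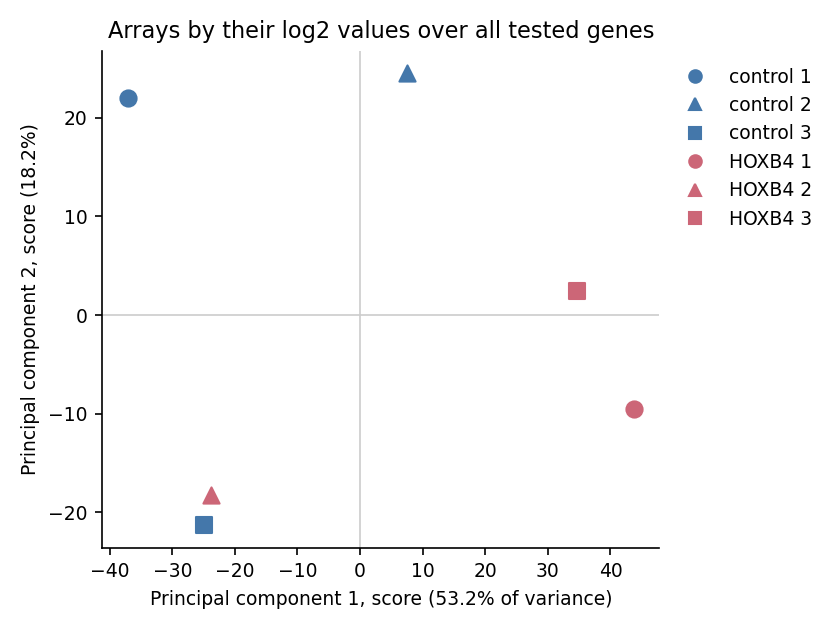
Scores of the 6 arrays on the first (53.2% of the variance) and second (18.2%) principal component of their log2 values over all tested genes, controls in blue and HOXB4 cells in red. HOXB4 2 (-23.8) lies beside control 3 (-25.0) on the first component, and control 2 (7.46) lies between the other controls and HOXB4 1 and 3.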

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

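The number of genes was 0 under all alternatives fixed beforehand that kept the 6 arrays, and 0 to 46 when 1 array was left out (0 to 3 higher, 0 to 43 lower), the highest without HOXB4 2. Without both second arrays, chosen after the data were seen and for their place on the leading axis, 817 genes were called, 502 higher and 315 lower. All 46 genes were among these 817, and the choice of arrays favours such calls. With the first principal component as a covariate, also chosen afterwards, 0 genes were called. The number of called lists was 3 with cyclic loess, 5 over all features, 0 with an estimated correlation and 0 with fry, against 10, and 5 to 14 when 1 array was left out (5 without control 1, 14 without HOXB4 2). It was 13 without both second arrays and 11 with the component as a covariate. With this covariate 4 of the 10 lists kept their call (Hox cluster, cardiac, cell cycle and pluripotency), the cardiac mean was -0.25, the ribosomal call ended (adjusted p = 0.062), the endothelial list was called lower (adjusted p = 4.7e-07), and 6 other lists were called, among them primitive streak (0.26, adjusted p = 0.0036), erythroid (0.17, adjusted p = 0.040) and interferon genes (0.21, adjusted p = 7.0e-05) as higher, whereas without both second arrays these 3 were called lower (-0.85, -0.47 and -0.26; adjusted p = 2.6e-06, 0.0071 and 0.044). The component was computed from these same values and sets HOXB4 1 and 3 apart from controls 1 and 3. With it the group term leans on control 2 and HOXB4 2, which the other fit leaves out. HOXB4 2 had the highest mean of the 6 arrays in these 3 lists (8.04, 6.74 and 6.14). The adjusted p with the covariate rest on a component built from the tested genes and are no separate support. Any further cause was not tested. The difference of the feature shared by Hoxb4 and Mir10a ran from -0.17 to 0.17 when 1 array was left out, above 0 without control 2 (0.12) or HOXB4 2 (0.17), and was 0.32 without both second arrays. For Runx1 itself it ran from -0.15 to 0.21, below 0 without control 1 (-0.15), control 2 (-0.04) or HOXB4 1 (-0.07), with array weights (-0.0018), cyclic loess (-0.0064) and the component as a covariate (-0.088). Kdr turned to -0.03 without control 1 and -0.14 without HOXB4 1, in a range from -0.14 to 0.19, and to -0.22 with the covariate. With the covariate, Fli1 was at -0.18 and Flt1 at -0.27, and the means of the endothelial, adhesion and haematopoietic factor lists were -0.47, -0.094 and -0.084; the endothelial mean ran from -0.068 (without HOXB4 1) to 0.85 when 1 array was left out. The other named genes kept their sign; 10 of the 61 genes followed were called without HOXB4 2 and 24 without both second arrays. The replicate number as a block gave 0 genes and 10 lists, with 1294 genes at an unadjusted p of 0.05. Same-numbered arrays deviated from their groups in opposite ways (correlations of -0.40, -0.59 and -0.35 across genes), which an exchange of the labels of control 2 and HOXB4 2 would also bring about. With these labels exchanged the correlations were -0.30, -0.25 and -0.17. The arrays were treated as unpaired, and none correlated best with its own number; whether same-numbered arrays share an experiment is not given in the sources used here. Background medians of 3.06 to 3.15 limit what can be read of genes near that level.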

Other observations

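All tests in this part were chosen after the values were seen. Beside the genes of the lists, the microRNA features of one primary cluster lay higher in all HOXB4 arrays. Mir23a differed by 1.42 (SE 0.23), Mir27a by 1.57 (SE 0.29) and Mir24-2 by 1.34 (SE 0.40), with an adjusted p of 0.605 for each. The placental gene Plac1 differed by -1.54 (SE 0.29, adjusted p = 0.605), and it was among the 46 genes called without HOXB4 2.

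Control 2 and HOXB4 2 lay on the other side of the leading axis than the rest of their groups. Over the 947 genes that differed by more than 1 on the log2 scale between controls 1 and 3 and HOXB4 1 and 3, HOXB4 2 had a median position of 0.07 on the way from the former (0) to the latter (1), and control 2 one of 0.56, which joins 0.63 for the 638 genes higher in HOXB4 1 and 3 with 0.38 for the 309 lower ones. Correlations of the deviations weigh the leading axis most, so they cannot exclude a weaker stage or handling effect shared by same-numbered arrays. A shared effect strong enough to lead the deviations is argued against. Their highest correlation was -0.35 as labelled and -0.17 with the labels of control 2 and HOXB4 2 exchanged. Such an exchange stays open, since control 2 lies at the place of neither group, and so do an array labelled HOXB4 2 that may hold cells without HOXB4 and a difference in maturity of the sorted cells, which is untested here. The feature shared by Hoxb4 and Mir10a, highest in control 2 (4.96) and lowest in HOXB4 2 (4.24), with HOXB4 1 and 3 (4.93 and 4.74) above controls 1 and 3 (4.63 and 4.40), is ordered as an exchange would order it, but the Hox list means kept to the labelled groups, so these values do not decide.

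The Hox cluster genes were lower in HOXB4 cells, and 30 of the 33 lay below the median gene in mean level. A general fall of dim features is argued against, since lists matched on mean level had a mean median difference of -0.039, against -0.20 for the Hox list. The Hox list lay below all 10000 of them, which does not measure how rare its shift is. The matched lists were drawn gene by gene, whereas the Hox genes had an estimated correlation of 0.36. The endothelial list, whose mean turned without HOXB4 1, likewise lay above all of its matched lists. A chance split cannot be excluded by 10 splits. The real one gave the largest median shift, 0.20 (1 of 10), with 33 members on one side. The highest of the others was 0.19, with 32 members on one side, and a further split with a shift of 0.15 also had 32. An effect of HOXB4 on the endogenous clusters is a hypothesis that may be followed up, and so is a difference in regional or stage identity between the arrays.

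The 77 features of the related microRNA families Mir297, Mir466, Mir467 and Mir669 had 56 distinct profiles, of which 53 were above 0 with a median difference of 0.31. Counting repeated profiles once does not remove the pattern, since 41.1% of them had no overlap and were higher in HOXB4 cells. A shift of all short transcripts is argued against by the 846 other microRNA features, with a median of -0.015 and an SD of 0.25. The real split gave the largest shift of the 10 (1 of 10), and 10 splits are too few to exclude chance. The highest of the others was 0.26, with 52 of the 56 profiles on one side, and the next was 0.25, with 51. The families were picked after their values were seen, which favours the labelled split in its rank and in the counts above. These features share sequence and may read 1 locus or one another's transcripts, so they are not independent; Sfmbt2, whose intron holds the largest group of them, differed by -0.26 (SE 0.29). A rise of these microRNAs with HOXB4 remains a hypothesis.

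For the comparison as a whole, 3 arrays against 3 allow 10 splits, too few for a share under 0.05. The labelled split gave 0 genes, a count that any split reaches, and the highest other, controls 1 and 3 with HOXB4 2 against the rest, 628 (464 in one direction). For lists it gave 10 and the highest other 12, and 4 of the 10 splits gave at least as many. The split with 628 genes is the one that the first principal component shows, so it points to the same structure of the samples and is no separate evidence of it.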
